A study of Homo sapiens with 41 samples.

How the data were processed

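RNA sequencing of patient-derived xenografts of metastatic breast cancer was analysed in 41 libraries: 13 of ET-R, 6 each of PR-1, PR-2, PR-3 and PR-4, and 4 of TNBC-IM. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, total RNA was extracted with Trizol, and an outside provider prepared and sequenced the libraries by standard Illumina protocols. The authors deposited 1 table of raw counts of reads per gene, without normalization. The submitters' processing notes name FastQC 0.11.8, TopHat2 2.1.1, featureCounts without a version and Subread 1.6.3, and the genome builds GRCh38 and GRCm38, without giving each a role. How reads of the mouse host were handled, whether reads were trimmed and whether counting used strand are not given in the sources used here. Mouse reads counted on human genes would raise conserved genes of the stroma. Without strand, reads of a gene and of an antisense or overlapping gene cannot be told apart, and reads shared by near-identical copies (ribosomal proteins, histones, keratins of the KRT6 family, mitochondrial genes and SPANXB1) could be split or dropped.

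All 58721 gene identifiers matched GENCODE release 29 on GRCh38, from which positions were taken, and 27 symbols that differed were replaced by that release's symbols. Genes of the Y chromosome and XIST, TSIX, JPX and FTX (567 genes) were left out of every test, which left 58154 genes, and 14060 genes of the table had no read. Library totals ranged from 11.73 to 22.715 M counts, where 1 M is 1000000 counts. A total of 3 counts over a group, the number used as a floor for groups with no read, corresponded to 0.0142 CPM in ET-R, 0.0354 in PR-1, 0.0317 in PR-2, 0.0275 in PR-3, 0.0304 in PR-4 and 0.0370 in TNBC-IM. Ratios against a group with 1 to 3 counts carry exact Poisson intervals at a confidence level of 0.95.

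The tests, the samples in each fit, the gene lists and the rule for named genes were fixed before the data were examined. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 22412. All 41 libraries entered 1 fit with a coefficient per group, TMM scaling, robust dispersion estimates and edgeR 4.0.16's quasi-likelihood test (R 4.3.3, statmod 1.5.0), with Benjamini-Hochberg adjustment over genes. A gene was called at an adjusted p under 0.05 and a log2 fold change of at least 1 in size. The comparisons were the equally weighted mean of the 4 PR models against ET-R, each PR model against ET-R, TNBC-IM against ET-R and against the PR mean, an F test among the PR models (3 degrees of freedom), each of the 5 models against the mean of the other 4, and limma 3.58.1 on the mean log2 CPM of each model (prior count 2), which takes the model as the replicate with 3 residual degrees of freedom. Overlaps between comparisons that share the ET-R libraries were set beside simulated unchanged groups, independent lists and ET-R libraries split by odd and even number.

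Each of 21 gene lists and 10 lists of cell type markers was tested with camera on voom values at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation. Lists with under 5 measured members were not tested. The lists covered the CDK4/6-RB pathway, E2F and S phase, G2/M, the estrogen receptor program, luminal and basal epithelium, the epithelial-mesenchymal transition, interferon, antigen presentation, nuclear oxidative phosphorylation, mitochondrially encoded genes, glycolysis and hypoxia, receptor tyrosine kinases and RAS, PI3K-AKT-mTOR, DNA repair, inflammatory and NF-kB genes, cholesterol and lipid synthesis, p53 targets, histones, cytosolic ribosomal proteins and the unfolded protein response. The marker lists covered fibroblast, endothelial, pericyte and smooth muscle, lymphoid, myeloid, adipocyte, skeletal muscle, erythroid, neuroendocrine and hepatocyte genes.

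Named genes were the 10 largest and 10 smallest fold changes between the PR mean and ET-R among genes called the same way in all 4 PR models, the 6 largest and 6 smallest for TNBC-IM, the 4 largest and 4 smallest for each PR model, the 6 largest ranges among the PR models and the 5 smallest p in each direction of the model-level test, with at least 10 CPM in the higher group except in the last, and up to 4 members per list. A set of 20 genes was reported whatever its values (ESR1, PGR, ERBB2, CCND1, CDK4, CDK6, RB1, CCNE1, CCNE2, CDKN2A, CDKN1A, E2F1, MKI67, GREB1, TFF1, FGFR1, FGFR2, KRT5, KRT8 and VIM). The collagens COL1A1, COL1A2 and COL3A1 lay outside this rule and were added after the data were examined. Some genes that met the rule are not reported. Fold changes are given for genes with more than 3 counts in each group, and bounds or levels for the others.

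On simulated counts with known changes, genes were counted as found at an adjusted p under 0.05, without the minimum fold change of a call. The shares found are therefore not those of the calls reported. Among 21039 genes, the test of the PR mean against ET-R found 75.8% of 95 changed by 1 on the log2 scale. It found 95.6% of 91 changed by 2. There were 5 false calls, or 0 with the minimum fold change. The shares were 58.9% and 84.6% for PR-1 against ET-R, 59.1% and 80.6% for TNBC-IM against ET-R, 63.3% and 86.8% for TNBC-IM against the PR mean, and 54.3% and 85.7% for the test among the PR models (21059 genes). Camera found 5 of 5 changed lists and called 0 of 20 unchanged ones at the preset correlation in the comparison of the PR mean with ET-R (22412 genes), and likewise with an estimated correlation. The simulated genes were drawn independently of each other. The simulation therefore cannot show how either setting handles lists whose members vary together. No pair of libraries in a group held identical counts, and every pair differed by more than sampling noise (chi-square per degree of freedom at least 4.70 over genes with at least 20 counts). Alternatives were DESeq2 1.42.0, RLE factors, library size alone, no filter beyond 1 read, limma voom with quality weights, no minimum fold change, the replicate number as a block, only the libraries of the groups compared, other weights, and models or TNBC-IM replicates left out in turn. Subsets of the ET-R libraries, libraries that stood apart left out, mitochondrial genes left out, limma voom for 1 model against the other 4, list tests without each TNBC-IM replicate, ET-R replicate 8 or PR-4 replicate 1 or 5, and list medians with library size alone were alternatives chosen after the data were examined. GC content was removed per library by a loess curve (span 0.5) in 1 check.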

Results

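RNA of metastatic breast cancer grown as patient-derived xenografts, that is, human tumour tissue kept growing in mice, was sequenced in 41 libraries of 6 groups. ET-R (n = 13 libraries) was labelled resistant to endocrine therapy, which acts on the estrogen receptor, and sensitive to inhibitors of the cell cycle kinases CDK4 and CDK6. PR-1, PR-2, PR-3 and PR-4 (n = 6 each) were labelled resistant to palbociclib, a drug that inhibits these kinases. A sixth group (n = 4) was labelled TNBC-IM, which the labels do not spell out. The table held 58721 genes with a total of 11.73 to 22.715 M counts per library, where 1 M is 1000000 counts. Median depth was 15.976 M counts in ET-R, 15.062 M in PR-1, 15.948 M in PR-2, 16.398 M in PR-3, 18.73 M in PR-4 and 16.838 M in TNBC-IM. Levels are CPM, a gene's counts scaled to its library's total over the tested genes, adjusted by TMM. They are given as mean ± SD over libraries, and fold changes on the log2 scale ± standard error. For edgeR's tests the standard error was back-calculated, as the size of the fold change divided by the square root of the test's F value. It is therefore not a separate estimate of the spread. Replicates were labelled biological, but no label says whether they came from separate animals or whether the 13 ET-R libraries came from 1 tumour. The p-values therefore measure the spread between libraries of these named models, not between tumours of a class.

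The 6 groups fell into 2 sets by expression. PR-1, PR-2 and PR-3, which carried the highest levels of luminal and estrogen receptor genes, correlated with each other at 0.868 to 0.899 across genes (Spearman's rho of group means of log2 CPM, where genes are not independent replicates). ET-R, PR-4 and TNBC-IM, which carried the highest levels of basal keratins and mesenchymal genes, correlated with each other at 0.851 to 0.888. Between the 2 sets the correlations were 0.808 to 0.83, so that PR-4 stood nearer to ET-R (0.851) and to TNBC-IM (0.888) than to any other palbociclib-resistant model. The median correlation of a library with the mean of the rest of its group (Pearson's r across genes) was 0.98 to 0.989 in each group.

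**Figure D1:**
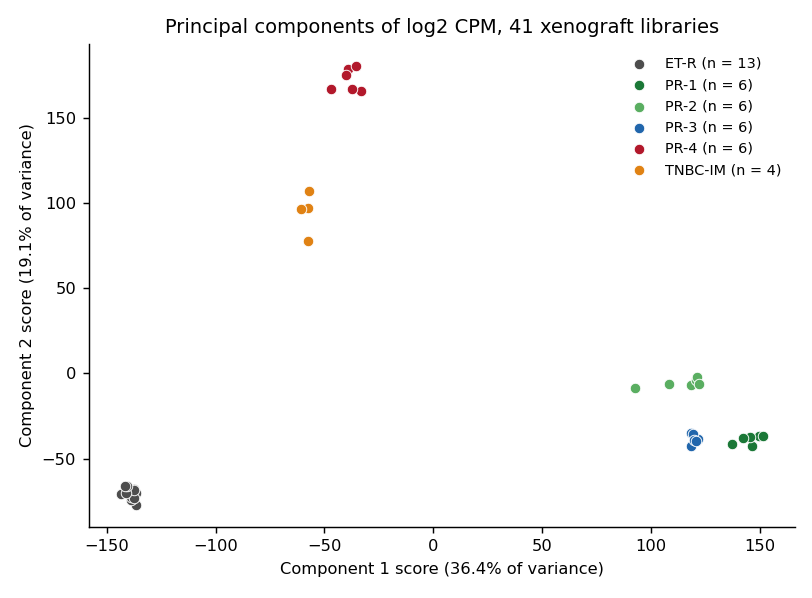
Principal components of log2 CPM over the tested genes, with 1 point per library coloured by group. The first component (x axis, 36.4% of the variance) and the second (y axis, 19.1%) place the libraries of each group together, with PR-1, PR-2 and PR-3 apart from ET-R, PR-4 and TNBC-IM.

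The first comparison set the mean of the 4 palbociclib-resistant models, each weighted equally, against ET-R, to ask how models that do not respond to palbociclib differ in expression from the model labelled sensitive to such drugs. In that mean, genes of the estrogen receptor pathway were higher than in ET-R. Genes of basal epithelium were lower by camera, a call that was lost with an estimated correlation (adjusted p = 0.111) and was not made in PR-4. ESR1, which encodes estrogen receptor alpha, stood at 0.767 ± 0.969 CPM in ET-R (n = 13) against 98.2 ± 18.0 in PR-1, 20.4 ± 4.48 in PR-2, 346 ± 76.4 in PR-3 and 24.2 ± 4.28 in PR-4 (n = 6 each), and was above every ET-R library in 24 of 24 resistant libraries. KRT14, a keratin of basal cells, fell from 1519 ± 256 CPM in ET-R to between 0.753 ± 1.28 in PR-3 and 112 ± 96.4 in PR-4. Of 22412 genes tested, 4348 were called higher and 5322 lower in the resistant models (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change). With all 24 resistant libraries weighted equally as 1 group the calls were 6197 higher and 3575 lower, which moved the share of higher calls from 45.0% to 63.4%. In 2003 of the genes tested a resistant model had no read in any library, so the fitted mean is undefined there, and 324 of these had p over 0.99.

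**Figure D2:**
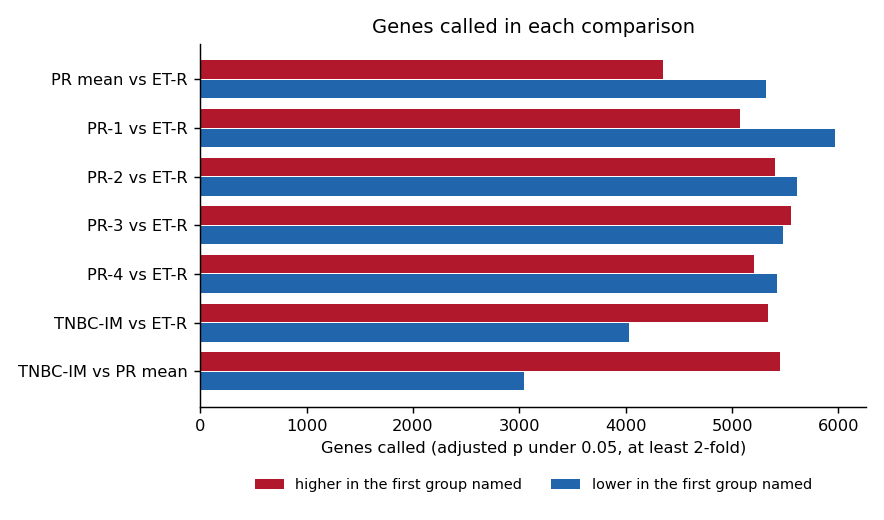
Genes called higher (upper bar of each pair) and lower (lower bar) in each comparison, out of 22412 tested. The x axis counts genes with an adjusted p under 0.05 and at least a 2-fold change, and the y axis names the comparisons. The mean of the 4 PR models against ET-R has 4348 higher and 5322 lower.

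The genes that rose most in the resistant models, by a rule that required the change in all 4 of them, were led by OLFM1 (ENSG00000130558.19, chromosome 9, 135075422 to 135121179, GRCh38), which encodes a secreted glycoprotein of the nervous system. OLFM1 had no read in ET-R and was at least 1380-fold (PR-4) to 5516-fold (PR-3) higher in the resistant models, against a floor of 3 counts over the ET-R group. TFF1, a secreted peptide induced by estrogen, rose by 10.22 ± 0.81 (ENSG00000160182.2, chromosome 21, 42362282 to 42366594), from 0.0976 ± 0.352 CPM in ET-R to 1889 ± 519 in PR-1 but only 1.75 ± 4.22 in PR-4 (0.0261 without library 2). LMF1, a lipase maturation factor, rose by 9.94 ± 0.28, FAN1, a nuclease of DNA repair, by 9.12 ± 0.24, EEF1A2, a translation elongation factor, by 9.07 ± 0.46, the calcium channel gene CACNA1H by 9.00 ± 0.43 and the metalloprotease gene MMP17 by 8.87 ± 0.26. GP2 and PTPRN2, also without a read in ET-R, were at least 59.9-fold and 24.2-fold higher in the models with the lowest levels, PR-3 and PR-4. CYP2J2 had 1 count in ET-R and a mean of 16.0 ± 4.61 CPM in PR-1, a ratio of 3387 (95% counting interval 608 to 133765). TFF1 was above every ET-R library in 19 of 24 resistant libraries, with the largest adjusted p of these fold changes (2.06e-13, edgeR's quasi-likelihood test).

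The genes that fell most were led by PEG3 (ENSG00000198300.13, chromosome 19, 56810077 to 56840728), an imprinted zinc finger gene. PEG3 stood at 1423 ± 212 CPM in ET-R, at 4.24 ± 4.61 in PR-1 (2.43 without library 3) and 17.1 ± 16.2 in PR-2 (10.8 without library 5), and had no read in PR-4, at least 46845-fold lower than ET-R. HAPLN1, a linker protein of the extracellular matrix, stood at 313 ± 89.3 CPM in ET-R against at most 0.821 ± 1.96 in a resistant model (PR-2), and the collagen gene COL11A1 at 23.99 ± 15.3 against at most 0.0731 ± 0.0778 (PR-4). OTOP1, a proton channel gene, stood at 42.3 ± 8.44 CPM in ET-R, RHOJ, a small GTPase gene, at 20.04 ± 1.53, the keratin gene KRT4 at 122 ± 38.2, the coagulation factor gene F13A1 at 14.1 ± 10.8, the neurofilament gene NEFL at 17.5 ± 6.46 and FAM83C at 13.5 ± 3.33, all against under 1 CPM in each resistant model. HIF3A, a subunit of the hypoxia-inducible factors, fell by 9.08 ± 0.40 (adjusted p = 5.33e-22, edgeR's quasi-likelihood test) and was below every ET-R library in 24 of 24 resistant libraries. Floors and counting intervals cover counting error only.

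In the estrogen receptor program, a list of 41 measured genes, 34 rose and 0 fell, and 34 and 0 when adjusted over the list alone (camera, adjusted p = 5.80e-13, and adjusted p = 0.0230 with an estimated correlation). GREB1, a cofactor of the estrogen receptor (ENSG00000196208.13, chromosome 2, 11482341 to 11642788), rose by 8.81 ± 0.37, the pioneer factor gene FOXA1 by 8.05 ± 0.32 and ESR1 by 6.40 ± 0.26 (ENSG00000091831.23, chromosome 6, 151656691 to 152129619). TFF3 stood at 0.355 ± 0.440 CPM in ET-R and 658 ± 165 in PR-1. The mean log2 CPM of the list was 1.79 in ET-R, 6.62 in PR-1, 4.79 in PR-2, 6.48 in PR-3, 3.23 in PR-4 and 2.71 in TNBC-IM. PGR, the progesterone receptor gene and a target of the estrogen receptor, did not follow the list in each model, with 0.533 ± 0.207 CPM in ET-R, 55.3 ± 27.5 in PR-1, 1.51 ± 1.48 in PR-2, 191 ± 53.4 in PR-3 and no read in PR-4. FOXA1 likewise stood at 1.21 ± 0.620 CPM in PR-4 against 342 ± 30.3 to 506 ± 27.9 in the other resistant models.

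**Figure D3:**
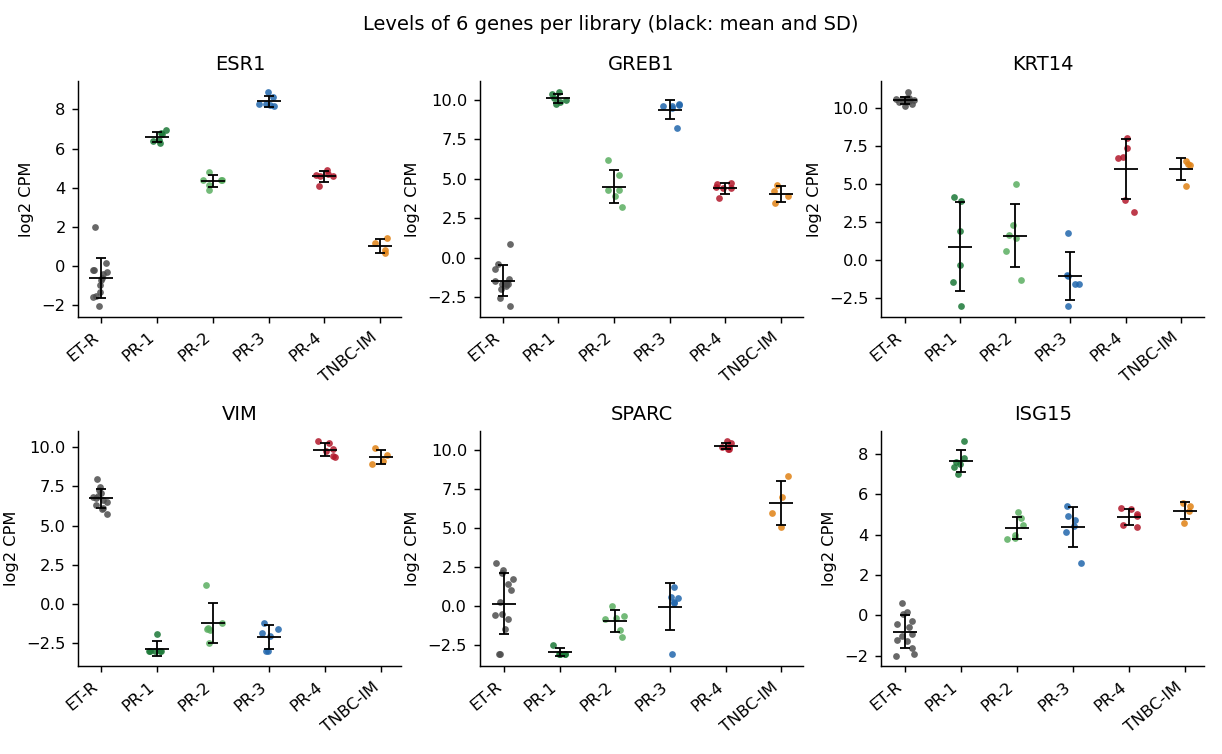
Log2 CPM of ESR1, GREB1, KRT14, VIM, SPARC and ISG15 in each library (points) with the group mean and SD (bar and whiskers), for the 6 groups on the x axis. A library with no read sits at the floor set by the prior count; ESR1 is lowest in ET-R and TNBC-IM, and VIM and SPARC are highest in PR-4.

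Basal and mesenchymal genes went the other way in the mean of the resistant models but not in PR-4. There the basal list had a mean log2 CPM of 6.13 against 5.77 in ET-R, and the mesenchymal list 5.31 against 3.32. Of 28 measured genes of basal epithelium 2 rose and 22 fell, and 2 and 22 when adjusted over the list alone (camera, adjusted p = 7.22e-06, but adjusted p = 0.111 with an estimated correlation). KRT14 fell by 7.61 ± 0.53 (ENSG00000186847.5, chromosome 17, 41582279 to 41586921), KRT5 by 6.54 ± 0.49 and DSG3, a desmoglein of squamous cell junctions, by 7.22 ± 0.38. Of 28 genes of the epithelial-mesenchymal transition 4 rose and 20 fell, and 4 and 20 over the list alone (camera, adjusted p = 0.0364, but adjusted p = 0.855 with an estimated correlation). SNAI2, a transcription factor of that transition, fell by 6.20 ± 0.32, while the collagen gene COL5A1 rose by 6.73 ± 0.40. VIM, the mesenchymal intermediate filament, showed how far the models diverged, at 116 ± 53.6 CPM in ET-R, under 1 CPM in PR-1, PR-2 and PR-3, and 954 ± 276 in PR-4 (ENSG00000026025.15, chromosome 10, 17228259 to 17237593). Markers of fibroblasts, a cell type of the stroma, moved with these lists, with 1 of 14 higher and 10 lower, and were not called as a list (camera, adjusted p = 0.319).

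Interferon-stimulated genes were higher in the resistant models. Of 41 measured 34 rose and 2 fell, and 34 and 2 when adjusted over the list alone (camera, adjusted p = 4.57e-07, but adjusted p = 0.831 with an estimated correlation). ISG15, a ubiquitin-like modifier induced by interferon (ENSG00000187608.9, chromosome 1, 1001138 to 1014540), rose by 6.33 ± 0.30, OASL by 5.82 ± 0.38 and XAF1 by 5.82 ± 0.67. ISG15 stood at 0.538 ± 0.378 CPM in ET-R and 214 ± 93.7 in PR-1. MX2, an antiviral GTPase, went against the list and fell by 5.91 ± 0.20, below every ET-R library in 24 of 24 resistant libraries. XAF1 stood at 15.7 ± 8.48 CPM in PR-1 but 0.0394 ± 0.0613 in PR-2, and was above every ET-R library in 18 of 24 (adjusted p = 1.53e-10, edgeR's quasi-likelihood test).

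Transcripts of the mitochondrial genome and of the cytosolic ribosome moved apart. Of 13 mitochondrially encoded genes 9 rose and 0 fell, and 9 and 0 over the list alone (camera, adjusted p = 6.86e-05, but adjusted p = 0.855 with an estimated correlation). MT-ND1, a subunit of respiratory complex I (ENSG00000198888.2, mitochondrial genome, 3307 to 4262), rose by 2.49 ± 0.16 and MT-CYB by 1.99 ± 0.14. The mitochondrial genome took 5.29 ± 0.600% of the counts in ET-R, 14.6 ± 4.84% in PR-1, 16.3 ± 3.18% in PR-2, 7.89 ± 1.30% in PR-3, 13.95 ± 2.15% in PR-4 and 7.89 ± 1.87% in TNBC-IM. Of 34 cytosolic ribosomal protein genes 0 rose and 20 fell, and 0 and 20 over the list alone (camera, adjusted p = 0.000235, but adjusted p = 0.855 with an estimated correlation). RPL13 fell by 2.03 ± 0.14 and RPL5 by 2.00 ± 0.10. The median of this list was −1.24, but −1.66 with ET-R libraries 7 to 13 alone and −0.49, with 2 genes higher and 10 lower, with libraries 1 to 6 alone. ET-R library 8 stood apart, with a list level of 11.67 in mean log2 CPM against 9.30 to 10.56 in the other ET-R libraries. It also had the fewest genes with a read in ET-R (20364, against 23088 to 30086). Within ET-R its shares of ribosomal RNA, with mitochondrial ribosomal RNA included (1.73%), and of counts in the top 50 genes (24.99%) were the highest. Library 12 came next within ET-R in each of these and in the list level. In PR-2 the share of ribosomal RNA was higher, at 2.18% to 4.07%. Whether the quality of the libraries moved the ribosomal protein genes was not tested. Without library 8 0 ribosomal protein genes rose and 14 fell, with a median of −0.84 (camera, adjusted p = 0.000205). Ribosomal protein genes have many processed copies in the genome and mitochondrial genes have nuclear copies, so their levels depend on how reads with several matches were counted.

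**Figure D4:**
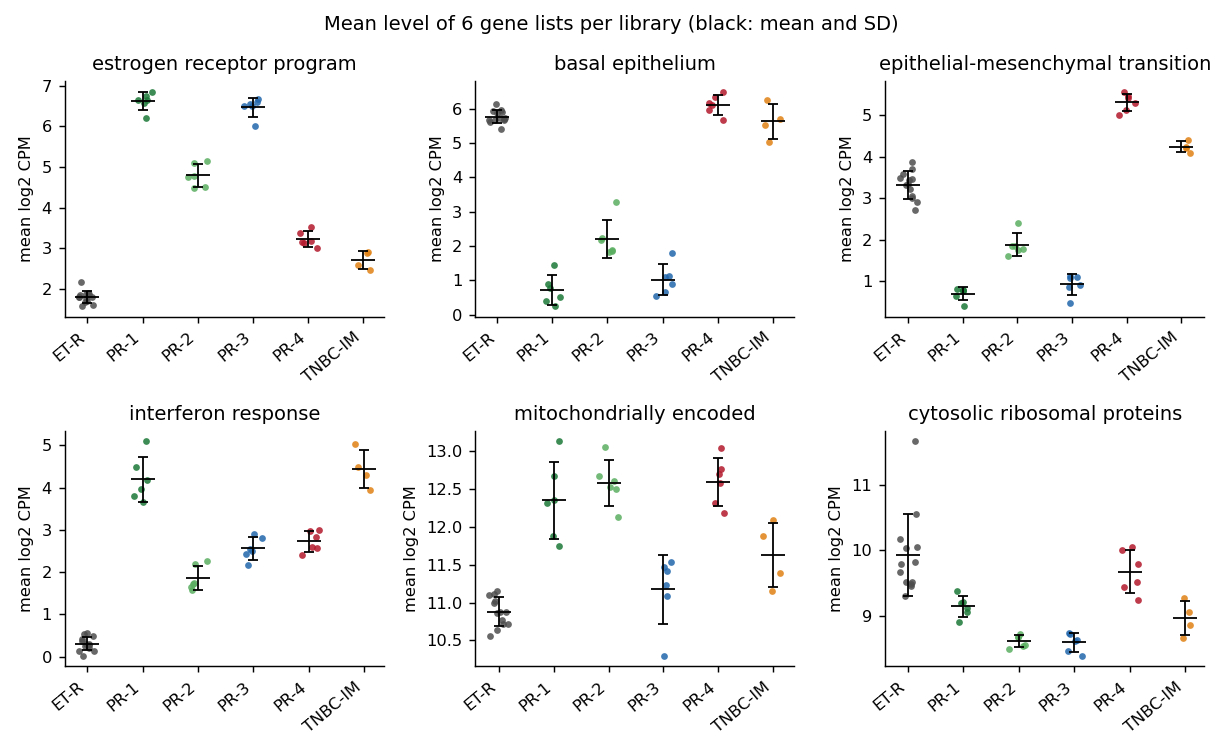
Mean log2 CPM of the members of 6 gene lists (estrogen receptor program, basal epithelium, epithelial-mesenchymal transition, interferon response, mitochondrially encoded, cytosolic ribosomal proteins) in each library, by group. Points are libraries and bars are group means with SD; the estrogen receptor program has a group mean of 1.79 in ET-R and 6.62 in PR-1.

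Among genes of cholesterol and lipid synthesis 5 of 26 rose and 2 fell, and 5 and 2 over the list alone (camera, adjusted p = 0.0207, but adjusted p = 0.855 with an estimated correlation). The isomerase gene IDI1 rose by 1.66 ± 0.09 and the sterol oxidase gene MSMO1 by 1.58 ± 0.09, while LSS, the synthase of lanosterol in the same pathway, fell by 2.22 ± 0.09. The other lists were not called by camera, and their counts over the list alone equalled those over all genes. Of 65 nuclear genes of oxidative phosphorylation 2 rose and 16 fell, among them SDHD by −2.40 ± 0.09 and ATP5F1A by −2.12 ± 0.07, but 8 rose and 10 fell with ET-R libraries 1 to 6 alone, and 1 and 20 with libraries 7 to 13 alone. Of 20 luminal genes 7 rose and 4 fell, with SPDEF, a luminal transcription factor, up by 5.62 ± 0.27 and KRT23 down by −5.21 ± 0.26. Of 21 antigen presentation genes 7 rose and 3 fell, with the immunoproteasome gene PSMB9 up by 5.53 ± 0.36. Among 33 receptor tyrosine kinase and RAS genes 9 rose and 9 fell, with RET up by 6.84 ± 0.27 and ERBB4 by 6.70 ± 0.34. Of 24 PI3K-AKT-mTOR genes 6 rose and 5 fell, with the phosphatase gene INPP4B up by 2.74 ± 0.21. Inflammatory cytokine and NF-kB genes counted 10 higher and 5 lower of 30, p53 targets 7 and 3 of 24, glycolysis and hypoxia 5 and 6 of 30, DNA repair 6 and 1 of 33, histone genes 3 and 1 of 18, and the unfolded protein response 4 and 1 of 20. For RTK and RAS signalling and for DNA repair the median was below 0 and camera's direction up, and for PI3K-AKT-mTOR the mean was below 0 with the median at 0.02 and camera up.

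The genes of the CDK4/6-RB pathway, which palbociclib acts on, did not move together: of 23 measured 6 rose and 7 fell, and 6 and 7 over the list alone (camera, adjusted p = 0.53). CDK6 fell by 3.84 ± 0.12 (ENSG00000105810.9, chromosome 7, 92604921 to 92836594), from 272 ± 42.1 CPM in ET-R to 35.2 ± 4.94 in PR-1, 8.33 ± 4.14 in PR-2, 3.19 ± 0.913 in PR-3 and 139 ± 33.7 in PR-4. CCND1, the gene of cyclin D1 (ENSG00000110092.3, chromosome 11, 69641087 to 69654474), rose by 2.28 ± 0.15 and reached 1411 ± 348 CPM in PR-3 against 127 ± 22.9 in ET-R. CCNE1, the gene of cyclin E1 (ENSG00000105173.13, chromosome 19, 29811898 to 29824308), fell by 2.33 ± 0.09. CDK4 rose by 1.02 ± 0.10 (ENSG00000135446.16, chromosome 12, 57747727 to 57756013), a value just past the 2-fold minimum that became 0.99, 0.99 and 0.90 without PR-1, PR-2 and PR-3, and 0.83 with ET-R libraries 7 to 13 alone. RB1, the retinoblastoma gene (ENSG00000139687.15, chromosome 13, 48303726 to 48599436), rose by 1.02 ± 0.11 and by 0.46 without PR-3. RB1 also missed the minimum, at 0.83 to 0.99, with library size alone, with limma voom, with the replicate block, without PR-2, with ET-R libraries 1 to 6 alone and with ET-R libraries 8 and 12 and PR-3 library 2 left out. It stood at 10.4 ± 2.12 CPM in ET-R, 63.0 ± 14.5 in PR-3 and 6.67 ± 1.33 in PR-4. CDKN2A, which encodes the CDK4/6 inhibitor p16 (ENSG00000147889.17, chromosome 9, 21967753 to 21995301), stood at 128 ± 47.7 CPM in ET-R, 9.06 ± 3.35 in PR-1, 36.4 ± 8.24 in PR-2 and 408 ± 59.2 in PR-4, and had no read in PR-3, at least 4668-fold lower than ET-R. Its neighbour CDKN2B also had no read in PR-3, at least 605-fold lower than ET-R.

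**Figure D5:**
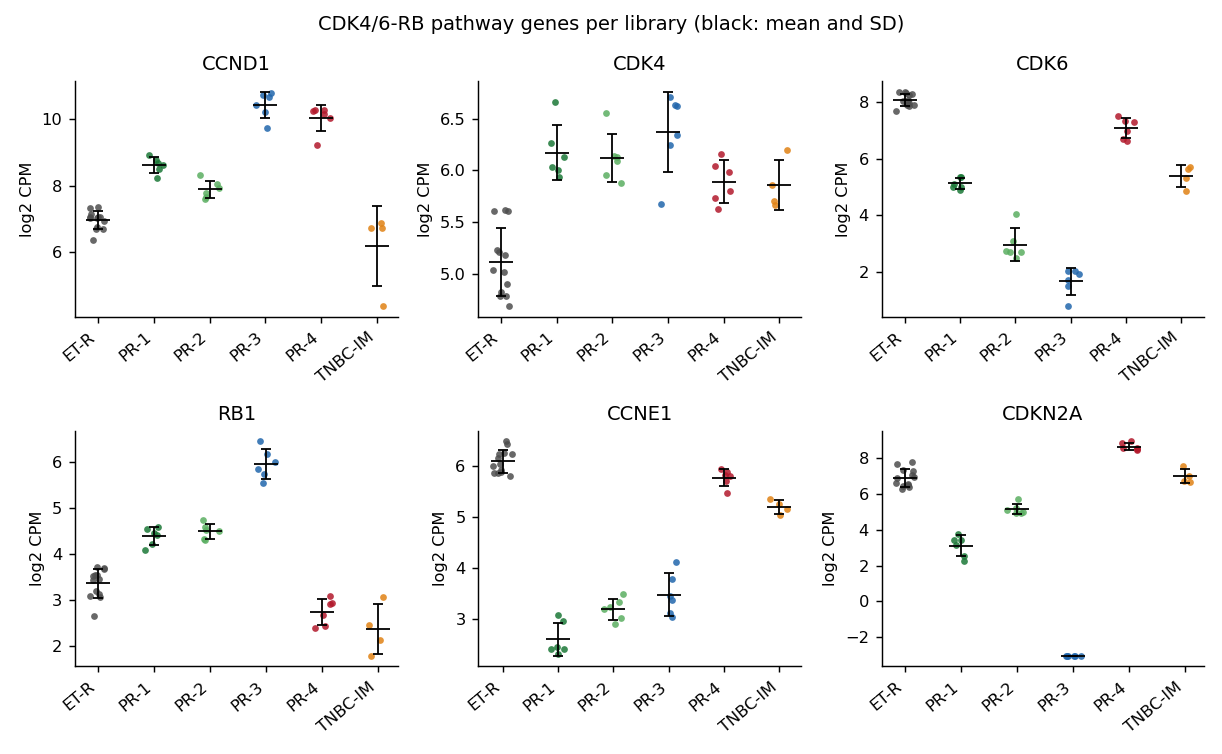
Log2 CPM of CCND1, CDK4, CDK6, RB1, CCNE1 and CDKN2A in each library (points) with the group mean and SD. CDK6 is lower in 24 of 24 resistant libraries than in every ET-R library, and CDKN2A sits at the floor in PR-3, where no library had a read.

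The cell cycle genes were not called as a list in the mean of the resistant models, which diverged. The mean log2 CPM of the G2/M list was 6.03 in ET-R, 5.63 in PR-1, 5.58 in PR-2, 6.35 in PR-3 and 6.13 in PR-4. That of the E2F list was 5.48, 5.26, 5.41, 5.99 and 5.88 in the same order. Camera called the E2F list higher in PR-3 and the G2/M list lower in PR-2, calls that were lost with an estimated correlation. Of 38 E2F and S phase genes 6 rose and 2 fell (camera, adjusted p = 0.448), with CDC6, a replication licensing factor, up by 1.84 ± 0.10, and of 38 G2/M genes 1 rose and 2 fell (camera, adjusted p = 0.65), with CDC20 down by −1.52 ± 0.08. The proliferation marker MKI67 (−0.19 ± 0.09), E2F1 (0.04 ± 0.10), CCNE2 (−0.08 ± 0.11), FGFR2 (−0.80 ± 0.15) and the CDK inhibitor gene CDKN1A (0.92 ± 0.19) were not called. KRT8, a luminal keratin, rose by 1.46 ± 0.11, above every ET-R library in 18 of 24 resistant libraries and below every one in 5 of 24. It stood at 429.8 ± 108 CPM in PR-4 against 778 ± 186 in ET-R. The growth factor receptor gene ERBB2 rose by 2.09 ± 0.08 over the models and by 0.68, short of the minimum, without PR-2. FGFR1 rose by 1.05 ± 0.14, above every ET-R library in 11 of 24, and by 0.52 without PR-3, 0.84 without PR-4 and 0.90 with ET-R libraries 7 to 13 alone. Its adjusted p of 7.83e-09 was the largest among the fold changes called between the resistant models and ET-R and named here (edgeR's quasi-likelihood test).

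Across the 4 resistant models 1388 genes were higher and 1766 lower than in ET-R in each. Unchanged groups simulated against the same ET-R libraries shared at most 0 genes in 20 simulations, and independent lists of the observed sizes would share 70.4 and 88.4. With PR-1 and PR-2 compared with the 7 odd-numbered ET-R libraries and PR-3 and PR-4 with the 6 even-numbered ones, the shared counts were 1293 and 1667, and 1268 and 1653 with the sets exchanged. These controls bear on the spread between libraries only. All 4 comparisons used the same ET-R model, so a gene peculiar to that model would be shared as well. The controls cannot separate such genes from a trait of the resistant models. Among the resistant models 17047 genes (76.1% of those tested) were called by edgeR's F test with 3 degrees of freedom and a range of at least 1 on the log2 scale, a test of 4 groups whose count cannot be compared with that of a single contrast. In all, 2685 genes went in opposite directions against ET-R in at least 2 of them. The largest ranges by the naming rule belonged to FDCSP, NID1, TNC, MSN, SPARC and SFRP1. FDCSP, a secreted peptide gene, NID1, a basement membrane gene, SPARC, a matricellular protein gene, and SFRP1, a WNT antagonist gene, were highest in PR-4, at 779 ± 383, 771 ± 239, 1250 ± 183 and 444 ± 99.7 CPM. NID1 and FDCSP had no read in PR-1, where they were at least 21788-fold and 22006-fold lower. TNC, the gene of the matrix protein tenascin C, peaked in PR-2 at 2491 ± 474 CPM, and MSN, which encodes moesin, had no read in PR-3 and 523 ± 102 CPM in PR-4.

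Set against the other 4 of the 5 models in turn, ET-R gave 9670 called genes, PR-4 9142, PR-3 7742, PR-1 7245 and PR-2 7142. ET-R had 13 libraries and each resistant model 6, so these counts differ in power and do not rank the models by distance. When each model counted as 1 replicate, limma on the 5 model means called 0 genes at adjusted p under 0.05 between ET-R and the resistant models, with 2074 at an unadjusted p under 0.05. Among the genes with the smallest p were OPLAH (7.50 ± 0.54), TJP1, PPP1R26 and EID1 on the higher side and H19 (−10.28 ± 0.76), HAPLN1, OTOP1, RHOJ and COL11A1 on the lower, the smallest adjusted p being 0.105. The same test called 4 genes for PR-3 and 0 for PR-1, PR-2 and PR-4, with 973, 680, 783 and 1765 at an unadjusted p under 0.05. OPLAH, an enzyme of the glutathione cycle, stood at 0.284 ± 0.174 CPM in ET-R and 55.0 ± 13.9 to 83.6 ± 19.2 in the resistant models. TJP1, the tight junction scaffold ZO-1, stood at 0.108 ± 0.153 CPM against 42.9 ± 5.95 to 76.1 ± 11.8. H19, an imprinted long noncoding RNA (ENSG00000130600.18, chromosome 11, 1995176 to 2001470), stood at 22525 ± 4678 CPM in ET-R and 16.1 ± 18.1 to 111 ± 244 in the resistant models, the last being PR-2 (11.7 without library 5). With 3 residual degrees of freedom this test found 9% of simulated genes changed by 6 on the log2 scale, so it could show only very large differences.

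PR-1 against ET-R asked the same question of a single model, and showed higher levels of estrogen receptor genes. TFF1 rose by 14.30 ± 0.88, GREB1 by 11.71 ± 0.41, CACNA1H by 12.24 ± 0.30 and KLHDC7B by 13.18 ± 0.56, each above every ET-R library in 6 of 6. ANKRD30A, a breast differentiation antigen gene, had no read in ET-R and was at least 5413-fold higher. At the other end IGF2BP3, an oncofetal RNA-binding protein gene, and the intermediate filament gene INA had no read in PR-1, at least 1727-fold and 1007-fold lower, and ACTG2 stood at 0.0275 ± 0.0428 CPM against 124 ± 53.7. VIM had 2 counts in PR-1, a ratio of 4930 in favour of ET-R (95% counting interval 1365 to 40706). MDM2, the negative regulator of p53, rose by 3.64 ± 0.12 to 733 ± 33.7 CPM and CDK6 fell by 2.95 ± 0.19. By edgeR's quasi-likelihood test, 5071 genes were higher and 5965 lower, and adjusted p was at most 3.17e-13 (DSG3) for the fold changes named for this model.

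Of the lists in PR-1, the estrogen receptor program had 36 of 41 higher and 1 lower (camera, adjusted p = 7.66e-18, and adjusted p = 0.00364 with an estimated correlation), and basal epithelium 1 of 28 higher and 24 lower (adjusted p = 4.50e-07, and adjusted p = 0.0483 with an estimated correlation). DSG3 fell by 9.45 ± 0.79. Interferon genes counted 36 of 41 higher and 2 lower (camera, adjusted p = 9.97e-13, but adjusted p = 0.214 with an estimated correlation), with OAS2 up by 9.23 ± 0.48 and IFI27 by 8.94 ± 0.45. Luminal genes counted 9 of 20 higher and 3 lower (camera, adjusted p = 0.0188, but adjusted p = 0.51 with an estimated correlation), with SPDEF up by 8.81 ± 0.30. Mesenchymal genes counted 3 of 28 higher and 22 lower (camera, adjusted p = 0.00113, but adjusted p = 0.33 with an estimated correlation). Mitochondrially encoded genes counted 9 of 13 higher and 0 lower (adjusted p = 0.00038, but adjusted p = 0.652 with an estimated correlation). Ribosomal proteins with 1 of 34 higher and 17 lower (adjusted p = 0.00668) and nuclear oxidative phosphorylation genes with 2 of 65 higher and 16 lower (adjusted p = 0.0204) were both called by camera and lost, at adjusted p = 0.867 with an estimated correlation. Counts adjusted over the list alone were equal for each of these lists.

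PR-2 was set apart by ERBB2, which encodes the receptor HER2 (ENSG00000141736.13, chromosome 17, 39687914 to 39730426). ERBB2 stood at 10299.9 ± 191 CPM in PR-2 against 139 ± 15.5 in ET-R, a change of 6.21 ± 0.11, and between 152 ± 33.8 and 344 ± 40.6 in the other resistant models. The mucin gene MUC19 reached 410 ± 121 CPM and the prolactin-induced gene PIP 274 ± 87.9 CPM, each with 1 count in ET-R, and ANKRD30A and GP2, without a read in ET-R, were at least 12942-fold and 9506-fold higher. ERBB4 rose by 8.69 ± 0.36 and DUSP4, a phosphatase induced by MAP kinase signalling, by 7.92 ± 0.35. RHOJ and the B cell receptor gene CD79B had no read in PR-2, at least 633-fold and 398-fold lower, while FAM171A1 had no read and FOXCUT, a noncoding neighbour of FOXC1, had 1 count, against 15.3 ± 2.20 and 27.6 ± 3.67 CPM in ET-R. In all, 5401 genes were higher and 5612 lower (edgeR's quasi-likelihood test), with an adjusted p of at most 1.41e-11 (KRT17) for the fold changes named for PR-2, each on the same side of every ET-R library in 6 of 6.

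In PR-2 the estrogen receptor program had 27 of 41 genes higher and 2 lower (camera, adjusted p = 2.03e-06, but adjusted p = 0.401 with an estimated correlation) and basal epithelium 3 of 28 higher and 19 lower (adjusted p = 0.000873, but adjusted p = 0.483 with an estimated correlation). KRT17 fell by 8.28 ± 0.80, to 2.43 CPM, or 0.636 without PR-2 library 5. Interferon genes counted 25 of 41 higher and 4 lower (camera, adjusted p = 0.0038), with MX2 lower by −5.81 ± 0.37. Mitochondrially encoded genes counted 13 of 13 higher (adjusted p = 8.37e-05), with MT-ND1 up by 2.80 ± 0.19, and ribosomal proteins 0 of 34 higher and 24 lower (adjusted p = 6.73e-06), with RPS18 down by −2.96 ± 0.29. Cholesterol and lipid synthesis counted 13 of 26 higher and 2 lower (adjusted p = 0.00145), with its regulator SREBF1 up by 2.75 ± 0.13. Among mitotic genes 2 of 38 rose and 8 fell (camera, adjusted p = 0.0142). These 5 calls were lost, at adjusted p = 0.648 with an estimated correlation. CDC6 rose by 3.92 ± 0.13 and CDK6 fell by 5.04 ± 0.22. Over each list alone the counts were equal.

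PR-3 had the highest ESR1, CCND1 and RB1 of the resistant models and no read of CDKN2A. ESR1 rose by 8.84 ± 0.30, GREB1 by 11.05 ± 0.41, CCND1 by 3.47 ± 0.19 and RB1 by 2.60 ± 0.14 against ET-R, while CDK6 fell by 6.41 ± 0.24. SPANXB1, a gene of the testis with near-identical copies on the X chromosome, stood at 191 ± 70.4 CPM with 2 counts in ET-R. OLFM1 was at least 5516-fold higher, the GTPase gene RHOH stood at 94.4 ± 15.3 CPM with 2 counts in ET-R, and SYTL5 at 118 ± 44.5 CPM against 0.0189 ± 0.0405. HAPLN1 and the mRNA decay factor gene ZFP36L1 had no read in PR-3, at least 11403-fold and 19166-fold lower, while PEG3 and the matrix proteoglycan gene BGN had 1 count each against 1423 ± 212 and 458 ± 171 CPM in ET-R. The test called 5556 genes higher and 5479 lower, and adjusted p was at most 1.14e-08 (HIST1H1B) for the fold changes named for PR-3, in 6 of 6 libraries each (edgeR's quasi-likelihood test). Library size in place of TMM scaling moved the median over all genes from 0.00 to 0.20.

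The estrogen receptor program in PR-3 had 38 of 41 genes higher and 0 lower (camera, adjusted p = 3.65e-18, and adjusted p = 0.00323 with an estimated correlation). Basal epithelium counted 2 of 28 higher and 22 lower (camera, adjusted p = 1.82e-06, but adjusted p = 0.0669 with an estimated correlation), with KRT14 down by −11.02 ± 1.19. Of 38 E2F and S phase genes 11 rose and 1 fell (adjusted p = 0.0099), with GINS1 up by 2.16 ± 0.10 and PCNA by 1.76 ± 0.11, and 9 of 33 DNA repair genes rose and 1 fell (adjusted p = 0.0291). Ribosomal proteins counted 0 of 34 higher and 25 lower (adjusted p = 1.82e-06), nuclear oxidative phosphorylation 2 of 65 higher and 18 lower (adjusted p = 0.0099), and glycolysis and hypoxia 4 of 30 higher and 11 lower (adjusted p = 0.049). These 5 calls by camera were lost, at adjusted p = 0.818 with an estimated correlation. Of 18 histone genes 10 rose and 0 fell (adjusted p = 0.0223), with HIST1H2AG up by 4.12 ± 0.29 and HIST1H1B by 3.76 ± 0.49. Interferon genes counted 29 of 41 higher and 5 lower (adjusted p = 2.51e-05), and mesenchymal genes 3 of 28 higher and 18 lower (adjusted p = 0.0099). These 3 camera calls were lost at adjusted p = 0.712 with an estimated correlation. Mitochondrially encoded genes were not called in PR-3, with 1 of 13 higher (camera, adjusted p = 0.506). Histone genes have near-identical copies, and counts over each list alone were equal.

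PR-4 was set against ET-R in the same way. Mesenchymal, antigen presentation and inflammatory genes were higher by camera, calls that were lost with an estimated correlation (adjusted p at least 0.519). SPARC rose by 9.24 ± 0.54 (ENSG00000113140.10, chromosome 5, 151661096 to 151687165), COL5A1 by 9.50 ± 0.44, VIM by 3.04 ± 0.27 and SOX10, a transcription factor of the neural crest and of basal-like tumours, by 10.69 ± 0.44, to 339 ± 66.2 CPM. FDCSP stood at 779 ± 383 CPM with 3 counts in ET-R, the oxidase gene DAO at 88.0 ± 25.8 with 1 count and the cadherin gene CDH19 at 65.3 ± 14.9 with 3 counts, and KLHDC7B rose by 11.37 ± 0.55. PEG3 and HOXB4 had no read in PR-4, at least 46845-fold and 579-fold lower, and RNF212 and OTOP1 had 2 counts and 1 count against 80.9 ± 10.1 and 42.3 ± 8.44 CPM in ET-R. CCND1 rose by 3.08 ± 0.19 and the neurotrophin receptor gene NTRK2 by 7.54 ± 0.28, while FGFR3 fell by 8.09 ± 0.36. KRT5 stood at 380 ± 188 CPM against 1060 ± 236 in ET-R and at most 5.04 ± 11.3 in the other resistant models, a value of PR-2 that was 0.426 without library 5. By edgeR's quasi-likelihood test 5206 genes were higher and 5426 lower, with an adjusted p of at most 3.36e-08 (ALB) for the fold changes named for PR-4, in 6 of 6 libraries each. Library size in place of TMM scaling moved the median over all genes from −0.04 to −0.21.

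Mesenchymal genes in PR-4 counted 18 of 28 higher and 3 lower (camera, adjusted p = 0.00124), antigen presentation 14 of 21 higher and 1 lower (adjusted p = 0.0012) and interferon genes 29 of 41 higher and 1 lower (adjusted p = 2.97e-05), or 30 and 1 when adjusted over the list alone. Fibroblast markers counted 6 of 14 higher and 3 lower (6 and 5 of 13 without PR-4 library 1), endothelial markers 4 of 10 and 3 and myeloid markers 3 of 5 and 1. These were not called by camera (adjusted p at least 0.496). Antigen presentation was highest in PR-4 library 5, and counted 13 higher and 4 lower without it (camera, adjusted p = 0.00281). CD74, the invariant chain of MHC class II, rose by 8.95 ± 0.32 and PSMB9 by 8.39 ± 0.38. Mitochondrially encoded genes counted 12 of 13 higher (adjusted p = 8.38e-05), with MT-ND1 up by 2.38 ± 0.19, and the estrogen receptor program 21 of 41 higher and 4 lower (adjusted p = 0.00779). Luminal genes counted 3 of 20 higher and 9 lower (adjusted p = 0.0153), with KRT23 down by −7.30 ± 0.54, and hepatocyte markers 5 of 5 higher (adjusted p = 0.0153), with ALB, the albumin gene, up by 5.46 ± 0.74 to 16.8 ± 9.14 CPM. The 7 camera calls of the mesenchymal, antigen presentation, interferon, mitochondrially encoded, estrogen receptor, luminal and hepatocyte lists were lost, at adjusted p = 0.519 with an estimated correlation. Inflammatory and NF-kB genes counted 22 of 30 higher and 2 lower (camera, adjusted p = 0.000347, but adjusted p = 0.718 with an estimated correlation), with IL32 up by 8.15 ± 0.52 and BIRC3 by 7.01 ± 0.44. Basal epithelium was not called, with 10 of 28 higher and 9 lower and a median of −0.38 against a mean of 0.50 (camera, adjusted p = 0.826). Apart from the interferon list, the counts over each list alone were equal.

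The TNBC-IM model was set against ET-R as a further reference. Interferon and antigen presentation genes were higher by camera, calls that were lost with an estimated correlation (adjusted p = 0.31 and 0.77). XAF1 rose by 9.96 ± 0.41, the interferon-induced chemokine gene CXCL10 by 8.41 ± 0.67, PSMB9 by 8.23 ± 0.39 and CD74 by 6.59 ± 0.31, each above every ET-R library in 4 of 4. FAN1 rose by 11.42 ± 0.26. Without TNBC-IM library 1 the group means of CXCL10, CXCL5, FDCSP and SOX10 became 3.77, 10.5, 6.17 and 55.8 CPM. The chemokine genes CXCL5 and CCL19 stood at 66.1 ± 112 and 35.5 ± 23.6 CPM with 1 count and no read in ET-R, FDCSP at 126 ± 239 and CDH19 at 116 ± 22.0 CPM with 3 counts each in ET-R, and ZNF560, without a read in ET-R, was at least 1756-fold higher. At the lower end were genes of the HOXB cluster, with HOXB6 at least 892-fold lower and HOXB3 at 1 count against 70.3 ± 12.7 CPM, PEG3 (−11.61 ± 0.83), RNF212 with 1 count against 80.9 ± 10.1 CPM, and KLK6 and IBSP without a read, at least 556-fold and 551-fold lower. CDK6 fell by 2.67 ± 0.22, the stress kinase gene TRIB3 by 8.50 ± 0.39 and KRT5 by 5.17 ± 1.02, while MKI67 rose by 1.27 ± 0.14, VIM by 2.59 ± 0.29, SOX10 by 8.79 ± 0.45 and GREB1 by 5.68 ± 0.41. ESR1 stood at 1.97 ± 0.508 CPM. In all 5339 genes were higher and 4035 lower, with an adjusted p of at most 3.78e-05 (KRT5) for these fold changes, in 4 of 4 libraries each (edgeR's quasi-likelihood test).

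Between TNBC-IM and ET-R, interferon genes counted 37 of 41 higher and 2 lower (camera, adjusted p = 1.37e-14) and luminal genes 1 of 20 higher and 8 lower (adjusted p = 0.000569), with EPCAM down by −1.80 ± 0.13, both at adjusted p = 0.31 with an estimated correlation. Antigen presentation counted 17 of 21 higher and 0 lower (adjusted p = 0.000214) and histone genes 2 of 18 higher and 12 lower (adjusted p = 0.0104), with HIST1H4H down by −3.77 ± 0.29, both at adjusted p = 0.77 with an estimated correlation. Inflammatory genes counted 24 of 30 higher and 0 lower, or 25 and 0 when adjusted over the list alone (camera, adjusted p = 0.0123), with the acute phase gene SAA1 up by 6.72 ± 0.60. This call rested on TNBC-IM library 1, whose list level was 5.12 in mean log2 CPM against 3.20, 1.84 and 1.84 in the other 3. Without it 13 of 30 inflammatory genes were higher and the list was not called (camera, adjusted p = 0.102), and SAA1 fell from 129 to 44.5 CPM. Nuclear oxidative phosphorylation counted 2 of 65 higher and 25 lower (adjusted p = 8.53e-06), with ATP5MF down by −2.26 ± 0.19, and ribosomal proteins 1 of 34 higher and 17 lower (adjusted p = 3.96e-05), with RPL18 down by −2.75 ± 0.27. The inflammatory, oxidative phosphorylation and ribosomal protein lists stood at adjusted p = 0.945 with an estimated correlation. The estrogen receptor program, with 16 of 41 higher and 3 lower, was not called (camera, adjusted p = 0.0534, but adjusted p = 0.0379 and 0.0228 without TNBC-IM libraries 3 and 4), nor were the hepatocyte markers, with 5 of 5 higher (adjusted p = 0.332). The p53 targets counted 9 of 24 higher and 2 lower, or 10 and 2 over the list alone, without a call. With library size in place of TMM scaling the median over all genes moved from 0.07 to 0.25, and the direction of no called list changed.

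Against the mean of the resistant models, TNBC-IM had higher basal, mesenchymal, interferon and antigen presentation genes and lower luminal and estrogen receptor genes by camera. These calls were lost with an estimated correlation (adjusted p at least 0.0765). PR-4 stood apart from that mean. Its mean log2 CPM was 6.13 against 5.63 in TNBC-IM for the basal list, 5.31 against 4.24 for the mesenchymal and 4.58 against 4.44 for the antigen presentation list. For the luminal list it was 5.81 against 6.01, and for the estrogen receptor list 3.23 against 2.71. ESR1 fell by 5.00 ± 0.40, FOXA1 by 7.84 ± 0.54, GREB1 by 3.13 ± 0.42 and TRIB3 by 10.50 ± 0.39. TFF1, TFF3, FAM110A, CEACAM6 and CLCA2 had no read in TNBC-IM, at least 51032-fold, 17789-fold, 2890-fold, 108-fold and 106-fold lower than PR-1 (CEACAM6 at least 40.6-fold without PR-1 library 3), and ALDH3B2 had 2 counts. Against PR-4 the bounds were 47.2-fold, 137-fold, 703-fold, 136-fold and 82.4-fold, and without PR-4 library 2 the means of TFF1, TFF3 and CEACAM6 in PR-4 were 0.0261, 0 and 0.0744 CPM. The cartilage proteoglycan gene ACAN stood at 1085 ± 812 CPM, the transcription factor gene PAX3 at 74.0 ± 32.4, the imprinted noncoding RNA MEG3 at 950 ± 516 and the prostaglandin synthase gene PTGS2 at 140 ± 127, against at most 8.20 ± 14.3, 0.173 ± 0.331, 9.51 ± 6.27 and 21.1 ± 7.54 in a resistant model. PTGS2 stood at 78.6 CPM without TNBC-IM library 1, and ACAN in PR-4 at 2.43 without library 6. CXCL5 and CCL19 were also among the 6 that rose most. SNAI2 rose by 6.74 ± 0.37, the chaperone gene CRYAB by 8.21 ± 0.42, MKI67 by 1.46 ± 0.13, FGFR2 by 3.75 ± 0.19, CDK6 by 1.17 ± 0.17 and CCNE1 by 1.42 ± 0.13, while CCND1 fell by 2.82 ± 0.27, RB1 by 1.98 ± 0.19, ERBB2 by 2.12 ± 0.13 and KRT8 by 2.17 ± 0.20. MKI67 and CRYAB were above, and ESR1, CCND1 and TRIB3 below, every resistant library in 4 of 4. SOX10, CD74, CDK6 and CCNE1 were above every resistant library in 0 of 4, SNAI2 in 2 of 4 and FGFR2 in 3 of 4. GREB1, ERBB2 and KRT8 were below every resistant library in 0 of 4, RB1 in 2 of 4 and FOXA1 in 3 of 4. ERBB2 was far higher in PR-2 than in the other resistant models, which raised the mean that TNBC-IM was set against. The test called 5451 genes higher and 3044 lower, with an adjusted p of at most 5.27e-08 (CDK6) for these fold changes (edgeR's quasi-likelihood test).

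The lists were also tested between TNBC-IM and the mean of the resistant models. The estrogen receptor program counted 1 of 41 higher and 26 lower (camera, adjusted p = 1.36e-08) and basal epithelium 23 of 28 higher and 1 lower (adjusted p = 1.86e-06), or 24 and 1 when adjusted over the list alone, both at adjusted p = 0.0765 with an estimated correlation. DSG3 rose by 5.72 ± 0.44 and SOX10 by 6.61 ± 0.36, with means of 36.8 and 55.8 CPM without TNBC-IM library 1 against 82.0 and 91.2 with it. SOX10 stood higher still in PR-4, at 339 ± 66.2 CPM. Mesenchymal genes counted 19 of 28 higher and 2 lower (adjusted p = 9.06e-05) and luminal genes 3 of 20 higher and 9 lower (adjusted p = 0.00024), with SPDEF down by −5.85 ± 0.45 to 1.40 CPM (0.816 without TNBC-IM library 2), both at adjusted p = 0.135 with an estimated correlation. SPDEF was below every resistant library in 0 of 4 TNBC-IM libraries. Fibroblast markers moved with the mesenchymal genes, with 8 of 14 higher and 0 lower, as did endothelial markers with 4 of 10 and 0 (3 over the list alone), skeletal muscle with 4 of 6 and 0 (5), hepatocyte with 3 of 5 and 0 (4) and pericyte markers with 3 of 6 and 1, none called by camera (adjusted p at least 0.121). Interferon genes with 27 of 41 higher and 2 lower (adjusted p = 5.68e-05) and antigen presentation with 14 of 21 higher and 1 lower (adjusted p = 0.00154), with CD74 up by 6.31 ± 0.29, were lost at adjusted p = 0.651 with an estimated correlation. Histone genes counted 0 of 18 higher and 11 lower (adjusted p = 0.000313, but adjusted p = 0.218 with an estimated correlation), with HIST1H1C down by −3.44 ± 0.28. Nuclear oxidative phosphorylation counted 1 of 65 higher and 12 lower (adjusted p = 0.00474, but adjusted p = 0.859 with an estimated correlation) and mitochondrially encoded genes 0 of 13 higher and 3 lower (adjusted p = 0.0391, but adjusted p = 0.803 with an estimated correlation, and adjusted p = 0.161 and 0.0744 without TNBC-IM libraries 1 and 4). Inflammatory genes counted 18 of 30 higher and 0 lower, or 19 and 0 over the list alone, and were not called by camera (adjusted p = 0.118), but were without TNBC-IM library 3 (adjusted p = 0.0136) or 4 (adjusted p = 0.00542), while 9 were higher without library 1. Library size in place of TMM scaling moved the median over all genes from 0.12 to 0.34, with no called list changing direction.

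Markers of other cell types that a xenograft could hold gave no further list called by camera between the resistant models and ET-R. Endothelial markers counted 3 of 10 higher and 5 lower, pericyte and smooth muscle markers 2 of 6 and 3, lymphoid markers 3 of 5 and 2, myeloid markers 3 of 5 and 1, skeletal muscle markers 1 of 6 and 4, neuroendocrine markers 2 of 8 and 1 and hepatocyte markers 1 of 5 and 0, with equal counts over each list alone. For the lymphoid list the median was 1.05 and the mean −1.11. Without ET-R library 8 the lymphoid markers counted 1 of 5 higher and 2 lower. Of the adipocyte markers 3 passed the count filter and of the erythroid markers 0, which was too few for a test. The collagen genes COL1A1, COL1A2 and COL3A1, the most abundant transcripts of fibroblasts, stood at 132 ± 54.0, 11.5 ± 3.15 and 1.69 ± 1.05 CPM in ET-R and 80.7 ± 78.8, 7.99 ± 12.4 and 33.1 ± 45.3 in PR-4, where they were 50.8, 3.003 and 15.8 without library 1.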

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

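Of the tests in this part, the exchange of labels, the ratio of collagens and the count of mesenchymal genes with library size alone were chosen after the result was seen, as were the alternatives with 2 sets of ET-R libraries or without mitochondrial genes.

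The estrogen receptor program was higher in the PR models than in ET-R, with 34 of 41 genes higher, although ET-R was the group labelled sensitive to CDK4/6 inhibitors. An exchange of the ET-R and TNBC-IM labels was argued against as the cause of this pattern. In TNBC-IM too, 26 of the 41 genes were lower than in the PR models. Both groups were low for the list, at 1.79 in ET-R and 2.71 in TNBC-IM in mean log2 CPM. The count therefore cannot show whether the labels were exchanged. Counts taken by mitochondrial transcripts were argued against by a median of 2.84 without those genes, against 2.85 with them, and a difference between 2 sets of ET-R libraries by 34 genes higher with each set alone. A difference between tumours that does not follow the response to palbociclib stays open: the gap between ET-R and the lowest PR model was 1.44 in mean log2 CPM, smaller than the range of 3.39 over the PR models. A link with the response may also be true, but 1 sensitive model cannot separate it from a difference between tumours.

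Mitochondrially encoded transcripts were higher and ribosomal protein transcripts lower in the mean of the PR models than in ET-R, except that PR-3 had 1 of 13 mitochondrially encoded genes higher (camera, adjusted p = 0.506) and the ribosomal protein list was not called in PR-4 (adjusted p = 0.28). Both camera calls of that mean were lost with an estimated correlation. The mitochondrial share of the counts was argued against, since the ribosomal protein median was −1.25 without mitochondrial genes and −1.24 with them. GC content as the whole cause was argued against by a ribosomal protein median of −0.89 after correction, from −0.96 in the same uncorrected values. A difference between 2 sets of ET-R libraries could not be excluded as part of the cause: the ribosomal protein median was −0.49 with ET-R libraries 1 to 6 alone and −1.66 with libraries 7 to 13 alone, and −0.84 without library 8, which was the highest of ET-R in this list and had the fewest genes with a read (20364). A biological difference between the tumours stays open and was not tested.

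Mesenchymal genes were higher in PR-4 and TNBC-IM than in the mean of PR-1, PR-2 and PR-3, with 25 and 23 of 28 called higher. Scaling was argued against by 23 of 28 called higher in each with library size alone. Reads of host stroma counted on human genes cannot be told apart from expression by the tumour: COL1A1, COL1A2 and COL3A1 together reached only 0.195 of the CPM of VIM and SPARC in TNBC-IM and 0.0552 in PR-4 (0.0332 without its library 1), but markers of stroma moved with the pattern. Fibroblast markers had a mean log2 CPM of 1.78 in PR-4 and 1.26 in TNBC-IM against −1.40 to −0.53 in PR-1, PR-2 and PR-3, and endothelial markers 0.49 and 0.50 against −1.40 to −0.87. A mesenchymal state of the tumour cells was not tested, since bulk libraries do not show which cells carried the RNA.

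ET-R was left out of the screen of single libraries, so its absence below says nothing about its libraries. Elsewhere, a gap to the next library was set against its group's range, at a level that chance passes in about 1 in 20 groups. It was passed by 1 of 20 library measures, 14 of 145 list levels and 29 of 358 gene levels, which are not independent of each other. PR-3 library 2 was lowest in its correlation with the rest of its group (gap 0.802 of the range). The same library was lowest in PR-3 for luminal (0.692), mitochondrially encoded (0.635) and lymphoid (0.636) lists. Its levels were also lowest for DUSP4 (0.681), EEF1A2 (0.773), FGFR3 (0.783), LMF1 (0.838), MT-ND1 (0.707), OPLAH (0.82), RPL18 (0.684), SPARC (0.765), SPDEF (0.717) and SREBF1 (0.678). PR-3 library 1 was lowest for the estrogen receptor program (0.726) and GREB1 (0.826).

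In PR-1, library 5 was lowest for MMP17 (0.779) and MSMO1 (0.692). In PR-2, library 5 was highest for the basal (0.718) and mesenchymal (0.699) lists, library 2 for cholesterol synthesis (0.791) and library 1 for lymphoid markers (0.748), while library 4 was lowest for skeletal muscle markers (0.637) and FAN1 (0.644). PR-2 library 6 was highest for FOXA1 (0.673) and LSS (0.703) and lowest for HIST1H2AG (0.65). In PR-4, library 5 was highest for antigen presentation (0.635), library 4 for the unfolded protein response (0.715), library 1 for fibroblast markers (0.666) and library 2 for TFF1 (0.9), and library 6 was lowest for CCND1 (0.755) and GREB1 (0.664).

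In TNBC-IM, library 1 was highest for p53 targets (0.942) and CXCL10 (0.836) and lowest for MKI67 (0.854), and library 3 was highest for fibroblast markers (0.833) and lowest for EPCAM (0.91). TNBC-IM library 4 was lowest for CCND1 (0.947), CCNE2 (0.966), KRT14 (0.839) and OASL (0.903) and highest for RPL18 (0.85) and SDHD (0.907).

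Effects against ET-R that pointed in opposite directions were compared among the PR models. Genes were kept because they were called in opposite directions and passed the F test whose p is given. Lists were kept because camera had called them in opposite directions in the same libraries. The p-values below are therefore not separate evidence. The fold changes of FGFR2 spanned 5.46 on the log2 scale, from −3.98 in PR-2 to 1.49 in PR-4 (adjusted p = 6.76e-19, edgeR's F test). INPP4B spanned 8.42, from −3.07 in PR-4 to 5.35 in PR-2 (adjusted p = 6.67e-21, edgeR's F test), and SPDEF 9.99, from −1.18 in PR-4 to 8.81 in PR-1 (adjusted p = 1.98e-20, edgeR's F test). By camera, the luminal list was higher in PR-1 than in PR-4 (adjusted p = 4.62e-06, and adjusted p = 0.0289 with an estimated correlation). The mesenchymal list was higher in PR-4 than in PR-1 (camera, adjusted p = 3.42e-08, and adjusted p = 0.0239 with an estimated correlation) and than in PR-3 (adjusted p = 2.96e-07, and adjusted p = 0.0352 with an estimated correlation).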

How the results depend on the processing

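ET-R libraries 1 to 6 or 7 to 13 alone, ET-R libraries 8 and 12 with PR-3 library 2 left out, mitochondrial genes left out, limma voom for 1 model against the other 4, list tests without each TNBC-IM replicate, ET-R replicate 8 or PR-4 replicate 1 or 5, and list medians with library size alone were chosen after seeing the data. Of 236 counts of calls under an alternative, 226 were within 1.5 times the count reported. The rest were larger, where more genes or fewer models entered the call. Without a filter beyond 1 read, 9988 genes were lower between the PR mean and ET-R (33.0% of its calls were higher) and 8745 higher in TNBC-IM than in the PR mean. Without a minimum fold change, 7472 were higher and 8989 lower between the PR mean and ET-R, 2632 and 3007 were shared by all 4 PR models, and 6457 and 5707 were lower in TNBC-IM than in ET-R and the PR mean. Without PR-4, the other 3 models shared 2336 higher and 2788 lower. DESeq2 called 4730 higher and 5332 lower between the PR mean and ET-R, and limma voom 5005 and 5326. Leaving out each TNBC-IM replicate in turn gave 5136 to 5362 higher and 3850 to 4075 lower against ET-R, and 5340 to 5522 higher and 2848 to 3120 lower against the PR mean. The model-level test called 0 genes under each of its 4 alternatives, with 2006 to 4624 genes at an unadjusted p under 0.05.

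With the replicate number as a replicate block, 4248 genes were higher and 5361 lower between the PR mean and ET-R, and among the named genes RB1 lost its call (0.84) and CDKN1A gained one (1.04). CDKN1A was also called without PR-2 (1.23) and with the PR libraries as 1 group (1.04). The same held with ET-R libraries 1 to 6 alone (1.07) and with ET-R libraries 8 and 12 and PR-3 library 2 left out (1.01). Libraries with the same number did not deviate together: of 80 pairs 2 correlated above 0.1 (−0.187 to 0.208), and 6 of 41 libraries correlated best with their own number in another group.

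Of the named genes' fold changes, 1742 of 1773 alternatives kept direction and call, 15 lost the call and 7 gained one. Those whose sign turned had not been called: E2F1 was −0.12 without PR-2, −0.0433 without PR-4 and −0.17 with ET-R libraries 7 to 13; CCNE2 was 0.17 without PR-4, 0.0104 with the 24 PR libraries as 1 group and 0.10 with ET-R libraries 7 to 13; MKI67 was 0.0259 with ET-R libraries 7 to 13. FGFR2 was 0.23 without PR-2 and 0.31 with the PR libraries as 1 group, but −1.34 without PR-1 and −1.58 without PR-4. The causes were not tested. Of 203 list tests 52 lost the call with an estimated correlation, and no direction turned. The 203 include the lists that camera had not called in the first place, so most camera calls were lost. The calls kept were the estrogen receptor program in the PR mean, PR-1 and PR-3 against ET-R, and basal epithelium in PR-1 against ET-R. Genes with 3 or fewer counts in a group are given as bounds or levels.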

Other observations

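The comparison of ET-R libraries 1 to 6 with 7 to 13 was chosen after the data were examined, and the comparisons behind the other splits were fixed before.

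H19 stood at 593 ± 398 CPM in TNBC-IM, against 22525 ± 4678 in ET-R. MDM2 (ENSG00000135679.23, chromosome 12, 68808176 to 68850686) reached 733 ± 33.7 CPM in PR-1 and 441 ± 86.4 in PR-3 against 58.8 ± 11.8 in ET-R.

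Histone genes had a mean log2 CPM of 4.23 ± 0.26 in PR-3 and 1.602 ± 0.044 in TNBC-IM, against 3.00 ± 0.24 in ET-R. Hepatocyte markers stood at 2.36 ± 0.45 in PR-4 and −1.36 ± 0.19 in ET-R, with ALB at 16.8 ± 9.14 CPM in PR-4 and 19.03 ± 32.6 in PR-2, where it was 6.06 without library 5. Which cells carried these transcripts was not tested.

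Within ET-R, libraries 1 to 6 and 7 to 13 differed at 5087 genes (adjusted p under 0.05, edgeR's quasi-likelihood test), of which 433 were at least 2-fold higher and 230 lower in libraries 7 to 13. The fold changes correlated with GC content across genes (Spearman's rho 0.51), and medians were 0.90 for ribosomal proteins, 0.50 for nuclear oxidative phosphorylation and 0.15 for mitochondrially encoded genes. The labels name no batch.

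Other splits of the same libraries into groups of the same sizes were compared for each count of called genes, 50 splits with the real one included. In each case 1 split, the real one, reached the count. For the comparisons fixed before, the other splits mixed libraries of different models, so this outcome could be foreseen. It shows only that the libraries follow their group labels. The real count and the highest other were 9670 and 810 for the PR mean against ET-R, 1388 and 0 for genes shared higher, 1766 and 0 for genes shared lower, and 17047 and 5386 among the PR models. They were 11036 and 2780 for PR-1, 11013 and 3342 for PR-2, 11035 and 2904 for PR-3 and 10632 and 2997 for PR-4 against ET-R. Against the other 4 models they were 7245 and 301 for PR-1, 7142 and 229 for PR-2, 7742 and 107 for PR-3 and 9142 and 1928 for PR-4. For TNBC-IM they were 9374 and 4767 against ET-R and 8495 and 1450 against the PR mean, and for the 2 sets of ET-R libraries, fitted alone, 684 and 4, where the division was chosen because the sets looked different. Libraries of a model resemble each other, so these splits do not bear on whether ET-R differs from the PR models as a class: with the model as the replicate limma called 0 genes for ET-R (2074 at an unadjusted p under 0.05) and also 0 for PR-1, PR-2 and PR-4 (680, 783 and 1765) and 4 for PR-3 (973), and 1 model against the other 4 gave 7142 to 9670 calls. The last counts come from models with unequal numbers of libraries, with the most in ET-R.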
